A study of Mus musculus with 9 samples.

How the data were processed

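Right ventricular myocardium of banded (5 arrays) and sham-operated (4 arrays) male C57BL6J mice was profiled on one-colour Affymetrix mouse expression arrays. According to the labels, mice were anaesthetised with isoflurane, the ventricle was excised and frozen in liquid nitrogen, RNA was isolated with a column kit, and labelling followed the manufacturer's standard protocol. The deposited values are log2 expression per probe set, background corrected and normalised between arrays by the authors. The submitters' processing notes name RMA and GCRMA without version, role or order, and state no filter. The values ran from 2.198 to 16.43, and dim probe sets piled up at a floor of 2.198 shared by all arrays, so the log2 scale was read from the range. No value was transformed or normalised again in the main analysis.

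The table held 45101 probe sets. The 64 control probe sets were left out, as were 9160 that named no gene and 932 that named several. The remaining 34945 named 18193 genes, and each gene was represented by the probe set with the highest mean over all 9 arrays, a choice blind to group. No filter on dim genes was applied. A group was called dim when its mean lay under 4.198, which is 2 log2 units above the floor. Where 1 group was dim, the fold was computed against that limit and is given as "at least", and where both were dim no fold is given. There were 7180 genes dim in both groups and 2854 at a single level on all arrays, and 163 of the genes past the threshold were dim in both groups.

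Banding was compared with sham in limma 3.58.1 under R 4.3.3 with lmFit and eBayes, without trend, robust fitting or covariates, two-sided, with Benjamini-Hochberg adjustment over all 18193 genes. The threshold was an adjusted p of 0.05 with no minimum fold. Differences are banding minus sham on the log2 scale with the standard error. The labels give no batch, so none was modelled. The fit was tested on simulated data with 50 changed genes at each size. It called 42% at 0.5 log2 units, 76% at 1, 96% at 2 and 98% at 3, with 11 false calls among 17993 unchanged genes. Only 200 genes were changed, all above the dim level, and the noise was independent between genes. The rates therefore do not describe dim genes or data in which many genes change together. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

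The gene lists and cell type markers were written before the data were examined, as were the comparison, the tests and the main alternatives. They covered chemokine ligands, chemokine receptors and both joined, small leucine-rich proteoglycans, matrix, TGF-beta, cardiac, metabolic, stress, proliferation, immune and clock genes, and markers of cell types, 43 lists in all. The marker lists share genes with the others, among them Postn, Tnc and Ccr2. Each list was described by the count of members past the threshold over all genes and adjusted over the list alone. It was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, all adjusted over the lists. Camera compares a list with the other genes. The directional test of fry asks whether a list's genes move one way on balance, and its mixed test whether they change in either direction. A list of liver genes was written after liver transcripts were seen among the largest falls, with 39 measured members whose values had not been looked at. A liver index was computed per array as the mean scaled linear value of the liver genes, both those already seen and those held out. Only genes above the dim level on some array entered it. The index was 1 on sham replicate 4 and 0.115 or less on every other array, so as a covariate it mostly marks that array.

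Genes named in the text followed a rule written before the data were examined. It took the 10 largest rises and the 10 largest falls among genes past the threshold whose groups did not overlap, leaving out clone, model and sequence names. It took up to 8 members with the smallest p of the chemokine and proteoglycan lists past the threshold, up to 4 members with the smallest p of every other list, and a fixed set of chemokine, proteoglycan, cardiac and matrix genes whatever their p. Not every gene the rule allows is named. Genes outside it were chosen after their values were seen, namely Timd4, Folr2, Cd163, Arntl, Ciart, Hk1, Pfkm, Pgam1, Pgam2, Hmox1, Arg1 and Hp.

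Technical measures per array were compared by exact permutation over all splits into groups of 5 and 4, two-sided, whose smallest p is 0.00794. The planned measures were the median, the interquartile range, the 3' minus 5' difference of the Actb and Gapdh controls and the means of 4 marker lists, adjusted as 1 family. The hybridisation controls, the percentage at the floor and the liver measures were added later.

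The alternatives were the mean of all probe sets of a gene, leaving out probe sets prone to cross-hybridisation, all probe sets tested singly, a filter on dim genes, quantile normalisation, centring each array on its median, a floor at the 20th percentile, trend with robust fitting, array weights, a replicate block, leaving out each array in turn, a 1.5-fold minimum and an adjusted p of 0.01. Added after seeing the data were the liver index as a covariate, leaving out sham replicate 4 with banding replicate 5, and a floor at the dim level. All probe sets tested singly, the 1.5-fold minimum and the adjusted p of 0.01 gave counts of genes only. Ranges given for a gene over the alternatives leave them out.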

Results

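The right ventricle pumps blood into the lungs. Pulmonary banding ties a band around the pulmonary artery, so that the ventricle works against a raised pressure, while sham mice undergo surgery without the narrowing. The samples were right ventricular myocardium of male C57BL6J mice aged 6 to 8 weeks. Total RNA was hybridised to one-colour Affymetrix mouse expression arrays, with 5 arrays of banded and 4 arrays of sham ventricles. The study's design text gives the number 5 for banded and sham mice, which can be read as 5 of each, and whether a sham array is missing is not given in the sources used here. Time since surgery, collection time and array batch are not given in the sources used here. The labels number the replicates without stating that each is a separate animal, so each p-value measures the spread between these samples. The 45101 probe sets held log2 expression values from 2.198 to 16.43, and array medians lay between 3.23 and 3.31. The number of arrays limits the precision. Pairs of arrays correlated across the 18193 genes at 0.993 to 0.997 within the banding group, at 0.983 to 0.997 within the sham group and at 0.945 to 0.977 between groups. Principal components were taken over the 10748 genes with a mean above the dim level. The first held 84.4% of the variance and placed the banding arrays between -60.4 and -34.0 and the sham arrays between 56.2 and 67.7.

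The comparison of banded with sham ventricles asks which transcripts change when the right ventricle is overloaded, with chemokines and small leucine-rich proteoglycans as the families the study names. Of 18193 genes tested, 6989 (38.4%) passed the threshold of an adjusted p of 0.05. Expression was higher in banding for 3356 genes and lower for 3633. Changes of at least 2-fold were found for 1438 of the higher and 1058 of the lower genes, and changes of at least 3 log2 units for 143 and 130. Every banding array lay on one side of every sham array in 6680 of the 18193 genes, where chance gives such separation in 1.59% of genes, and 6368 of these genes were past the threshold. The median difference over genes above the dim level was -0.02.

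The largest rise was in Cthrc1, which rose by 9.07 ± 0.30 log2 units (SE, adjusted p = 8.51e-06), from 3.97 ± 0.45 in sham (SD, n = 4) to 13.04 ± 0.48 in banding (SD, n = 5), at least 458-fold. C1qtnf3 rose at least 105-fold (log2 8.28 ± 0.40, adjusted p = 1.7e-05), and Tnc at least 61.4-fold (7.14 ± 0.15, adjusted p = 8.72e-07). Sprr1a, a gene of the cornified envelope family, rose at least 43.7-fold (7.13 ± 0.83, adjusted p = 0.000409). Sfrp2 rose 99.6-fold (6.64 ± 0.31) and Ptn 76.7-fold (6.26 ± 0.25). The other largest rises were in Col12a1 (at least 55.7-fold), Ltbp2 (at least 67.1-fold), Col11a1 (at least 25.9-fold) and Col8a2 (at least 29.8-fold). "At least" marks a gene whose lower group was dim, so its fold is a lower bound. With the mean of all its probe sets, a gene's rise was 3.60 log2 units for Tnc, 2.52 for Col12a1 and 4.31 for Ptn.

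The 10 largest falls were all in genes that the liver expresses at high levels. Alb, which encodes albumin, fell by 8.85 ± 1.40 log2 units (adjusted p = 0.00168), at least 399-fold. Ttr changed by -8.26 ± 1.10 log2 units, or by -7.82 with values floored at the dim level, under which 4 of its 5 banding values lay. Serpina1c (at least 132-fold), Fabp1 (at least 125-fold), Serpina1b (at least 115-fold), Apoa1 (at least 145-fold), Hpx (at least 92.2-fold), Fga (at least 83.1-fold), Cyp3a11 (at least 50.6-fold) and Fgg (at least 35.4-fold) were also lower. Levels varied within the groups. Alb stood at 12.73, 12.32, 11.45 and 14.85 on sham replicates 1 to 4, and at 2.34, 2.71, 3.31, 3.08 and 8.51 on banding replicates 1 to 5. Single arrays moved the size of each of these falls by more than 1.5-fold, and all 10 stayed past the threshold without any 1 array. Without sham replicate 4 the log2 differences lay between -8.18 for Alb and -6.14 for Fgg. Without banding replicate 5 they were -9.98 for Alb, -8.85 for Serpina1b and -9.08 for Ttr, and without sham replicate 3 they were -8.59 for Fga, -7.67 for Hpx and -7.76 for Fgg. Across 39 further liver genes, held apart from the choice of these, the mean was 5.72 ± 1.95 in sham (SD, n = 4) and 2.81 ± 0.09 in banding (SD, n = 5), with an exact permutation p of 0.00794, the smallest that these group sizes can give. Without sham replicate 4 the sham mean was 4.79 ± 0.67 (SD, n = 3) and the difference -1.98, against -2.91 with it. Of these 39 genes, 19 were past the threshold and lower in banding, and Arg1 (-0.61) and Hp (-0.46), chosen after their values were seen, were above the dim level in both groups and did not pass.

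**Figure D1:**
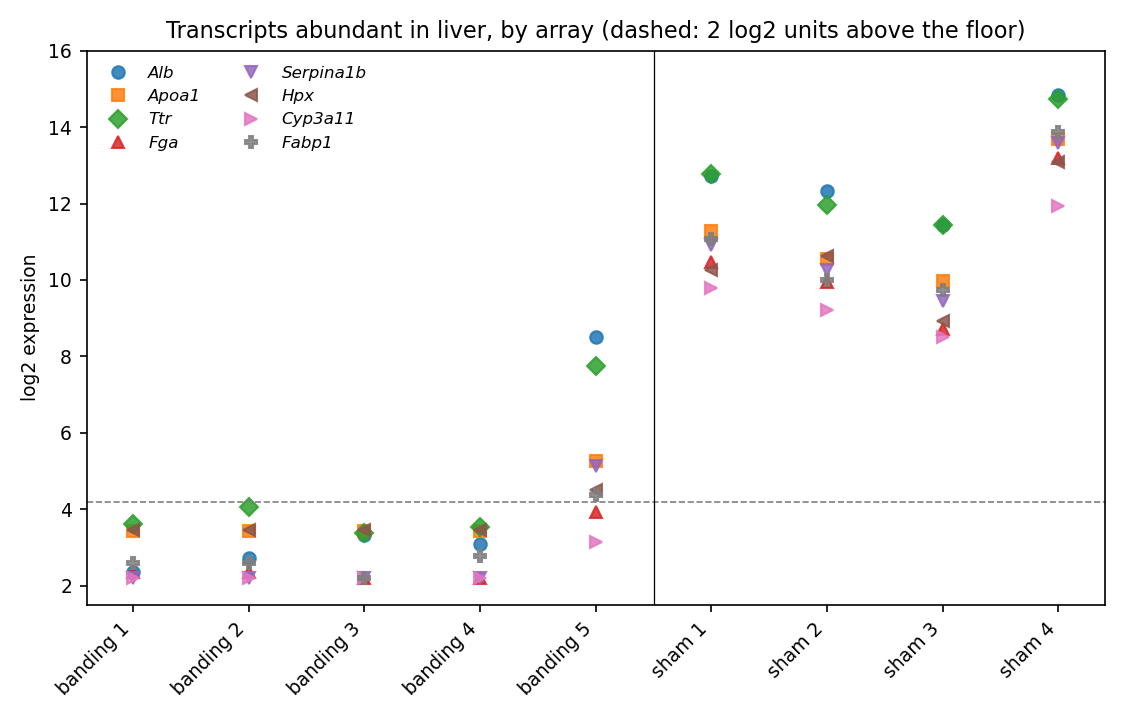
Log2 expression (vertical axis) of 8 genes abundant in liver on each of the 5 banding and 4 sham arrays, each point 1 gene, with a dashed line at the dim level. Alb reached 14.85 on sham replicate 4 and 8.51 on banding replicate 5, where the other 4 banding arrays lay between 2.34 and 3.31.

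Small leucine-rich proteoglycans are matrix proteins that bind collagen fibrils and growth factors. Of 15 measured on the list, 10 were higher in banding, 0 were lower and 5 did not pass, and 10 passed when adjusted over the list alone. The list as a whole was shifted upwards (camera adjusted p = 0.000139), but not with an estimated correlation (adjusted p = 0.381). Aspn rose 17.5-fold (log2 4.13 ± 0.19, adjusted p = 1.37e-05), and Fmod rose 16.2-fold (4.02 ± 0.24, adjusted p = 3.3e-05), or by 4.67 log2 units without cross-hybridising probe sets. Bgn, which encodes biglycan, rose 7.84-fold (2.97 ± 0.13, adjusted p = 1.26e-05). Smaller rises were found for Omd (3.22-fold, adjusted p = 0.0037), Lum (3.12-fold, adjusted p = 7.39e-05), Ogn (1.92-fold, adjusted p = 0.000207) and Ecm2 (1.32-fold, adjusted p = 0.00211). Epyc rose at least 4.61-fold (adjusted p = 0.00745). Dcn, which encodes decorin, rose 1.37-fold (0.45 ± 0.10, adjusted p = 0.00987), from 13.61 ± 0.05 in sham (SD, n = 4) to 14.07 ± 0.21 in banding (SD, n = 5). With the mean of its probe sets Dcn no longer passed (log2 0.33, adjusted p = 0.0609), and over the alternatives that tracked single genes its adjusted p ran from 0.00412 to 0.0609.

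Among 56 chemokine ligands and receptors, 15 were higher, 4 were lower and 37 did not pass, and 24 were dim in both groups. Of all 18193 genes 38.4% passed, so the count of passing members alone does not set this family apart. Adjusted over the list alone, 19 passed. The joint list was shifted upwards (camera adjusted p = 0.0245), but not with an estimated correlation (adjusted p = 0.383) and not when the level of liver transcripts was a covariate (adjusted p = 0.0552). Of 35 ligands, 10 were higher, 3 lower and 22 did not pass, with 13 passing when adjusted over the list alone and the list itself not passing (camera adjusted p = 0.175, 0.524 with an estimated correlation). Of 21 receptors, 5 were higher, 1 was lower and 15 did not pass, and 6 passed when adjusted over the list alone. The receptor list's camera adjusted p was 0.0255, against 0.383 with an estimated correlation, 0.0854 with arrays centred on their medians and 0.0546 with values floored at the dim level. On the same arrays 12 of 16 macrophage markers were higher and 3 lower, and Ccr2 is on both the receptor and the macrophage list.

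Cxcl10 rose 7.6-fold (log2 2.93 ± 0.29, adjusted p = 0.000202), Ccl8 6.26-fold (2.65 ± 0.53, adjusted p = 0.00516) and Cx3cl1 4.89-fold (2.29 ± 0.31, adjusted p = 0.000838). The rise of Cx3cl1 was 0.65 log2 units with the mean of its probe sets and still passed. Cxcl16 rose 3.72-fold (1.90 ± 0.15, adjusted p = 9.75e-05), Ccl12 3.45-fold (adjusted p = 0.0037), Ccl2 2.61-fold (adjusted p = 0.00774) and Cxcl12 1.68-fold (adjusted p = 0.00642). Ccl5 rose at least 2.45-fold (adjusted p = 0.00141). In the other direction, Cxcl14 was 6.14-fold lower (-2.62 ± 0.22, adjusted p = 0.000115), and Ccl11 was at least 5.22-fold lower (-3.72 ± 0.07, adjusted p = 5.87e-07). Cxcl13 did not differ by more than the spread between arrays, at 4.24 ± 0.58 in banding (SD, n = 5) and 4.12 ± 0.33 in sham (SD, n = 4; adjusted p = 0.909). Its difference of 0.12 became -0.06 without banding replicate 3 and reached 0.58 at the other end of its alternatives. A second, dimmer probe set of Cxcl13 differed by 0.71 ± 0.83. The sham mean lay under the dim level of 4.198 and the banding mean just above it, so a change in Cxcl13 could be missed.

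Among receptors, Ccr2 rose 8.40-fold (log2 3.07 ± 0.31, adjusted p = 0.000219), Cx3cr1 4.64-fold (2.21 ± 0.25, adjusted p = 0.00036) and Cxcr4 3.997-fold (1.999 ± 0.18, adjusted p = 0.000159). With the mean of its probe sets Ccr2 rose by 1.84 log2 units. Ackr1 rose at least 1.61-fold (adjusted p = 0.00812), but did not pass without sham replicate 4 and banding replicate 5 (adjusted p = 0.0508), with a range of 0.000648 to 0.0508 over its alternatives. Ccrl2 was 2.48-fold lower (adjusted p = 0.00101). Ccr1 rose 3.07-fold (adjusted p = 0.0183), and its call was lost without sham replicate 1 (log2 1.41, adjusted p = 0.0529), within a range of 0.00525 to 0.0692 over its alternatives. Cxcr6, the receptor of Cxcl16, just missed the threshold (2.72 ± 0.92, adjusted p = 0.051). Its banding values ran from 3.11 to 7.36 and its sham values averaged 2.59 ± 0.02 (SD, n = 4). Without banding replicate 1 it passed (3.27, adjusted p = 0.0165), and its adjusted p ran from 0.0165 to 0.273 over the alternatives. Cxcr5, the receptor of Cxcl13, lay at the floor in both groups. Ccl21a was not analysed here.

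**Figure D2:**
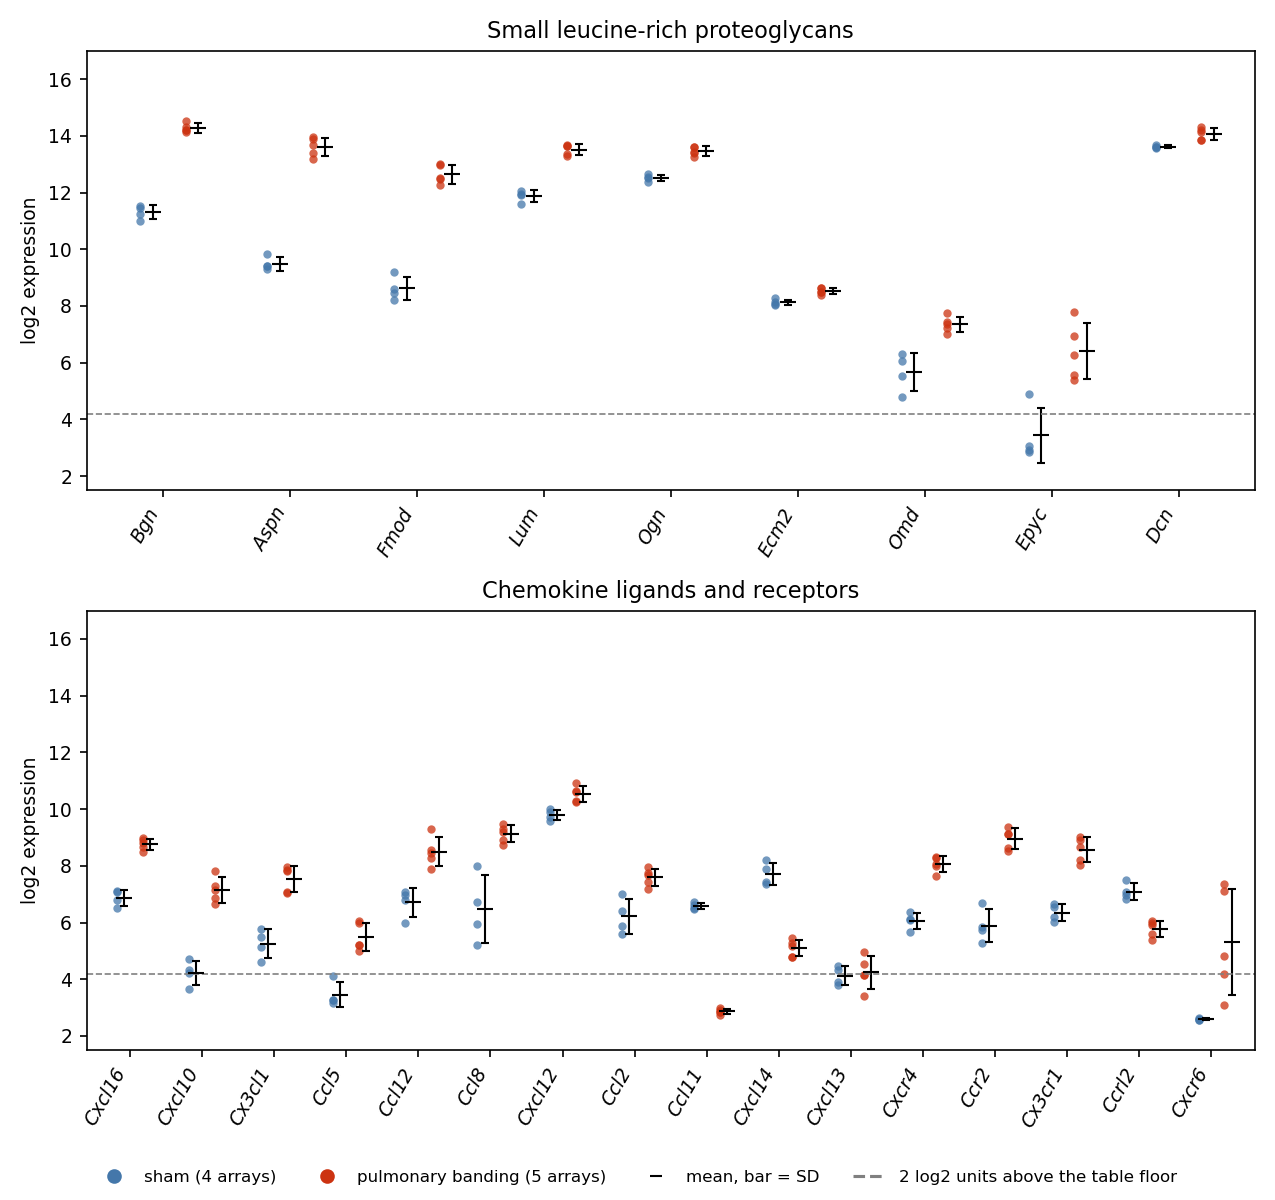
Log2 expression (vertical axis) of small leucine-rich proteoglycan genes and chemokine ligand and receptor genes, each point 1 of 4 sham or 5 banding arrays, with the mean, the SD as a bar and a dashed line at the dim level. Dcn averaged 13.61 in sham and 14.07 in banding, Cxcl13 4.12 and 4.24, and the banding values of Cxcr6 ran from 3.11 to 7.36.

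Other matrix lists were compared in the same way. Of 32 genes of collagens and collagen processing, 31 were higher, 0 lower and 1 did not pass (31 when adjusted over the list alone, camera adjusted p = 4.14e-19, 0.111 with an estimated correlation). Col1a1 rose 28.0-fold (log2 4.81 ± 0.19, adjusted p = 9.98e-06), Col5a2 16.1-fold, Col1a2 10.7-fold (adjusted p = 1.58e-06) and Col3a1 4.52-fold (2.18 ± 0.08, adjusted p = 9.56e-06). With the mean of the probe sets these were 3.69 log2 units for Col1a1 and 3.34 for Col3a1. Of 30 matrix glycoproteins, 26 were higher, 1 lower and 3 did not pass (28 when adjusted over the list alone, camera adjusted p = 1.58e-13, 0.0943 with an estimated correlation). Thbs4 rose 44.4-fold, Postn 25.2-fold (4.65 ± 0.17, adjusted p = 8.75e-06) and Sparc 4.36-fold, or by 1.52 log2 units with the mean of its probe sets. Of 23 matrix proteases and inhibitors, 13 were higher, 2 lower and 8 did not pass (17 when adjusted over the list alone, camera adjusted p = 9.44e-05, 0.0943 with an estimated correlation). Timp1 rose 37.7-fold (5.24 ± 0.32, adjusted p = 3.59e-05), Mmp14 13.5-fold and Mmp2 4.70-fold.

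In TGF-beta and activin signalling, 17 of 24 genes were higher, 1 was lower and 6 did not pass (18 when adjusted over the list alone, camera adjusted p = 2.59e-06, 0.0943 with an estimated correlation). All 3 Tgfb genes rose, with Tgfb3 7.38-fold higher (log2 2.88 ± 0.17, adjusted p = 3e-05), Tgfb2 5.40-fold (2.43 ± 0.31, adjusted p = 0.000651) and Tgfb1 1.71-fold (0.77 ± 0.14, adjusted p = 0.00347). Fstl1 rose 9.38-fold and Skil 3.03-fold.

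Of 21 cardiac stress genes, 14 were higher, 1 lower and 6 did not pass (15 when adjusted over the list alone, camera adjusted p = 0.000191, 0.383 with an estimated correlation). Myh7, the slow myosin heavy chain, rose 38.9-fold (log2 5.28 ± 0.44, adjusted p = 0.000107). The natriuretic peptide genes Nppb and Nppa rose 7.14-fold (adjusted p = 0.000132) and 6.78-fold (adjusted p = 0.00245), with Nppa at 12.44 ± 1.10 in sham (SD, n = 4) and 15.20 ± 0.13 in banding (SD, n = 5). Acta1 rose 2.92-fold (adjusted p = 0.00275), Ankrd1 2.69-fold and Ccn2, a growth factor of the glycoprotein list, 10.48-fold. Myh6, the fast myosin heavy chain, did not pass (-0.12 ± 0.05, adjusted p = 0.0829) except without banding replicate 1 (-0.15, adjusted p = 0.0297), and its adjusted p ran from 0.0297 to 0.375 over the alternatives. Its values of 16.14 to 16.39 lay near the highest in the table, 16.43, where a difference can be compressed. Sarcomere and Z-disc genes went both ways, with 4 of 23 higher, 9 lower and 10 not passing (13 when adjusted over the list alone). That list's mean difference was 0.15, its median -0.06 and its test downwards (camera adjusted p = 0.433, 0.781 with an estimated correlation). Tpm2 rose 3.74-fold, and Tnni3 was 1.87-fold lower (adjusted p = 0.00136).

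Calcium handling and ion channel genes were mostly lower, with 20 of 30 lower, 1 higher and 9 not passing (22 when adjusted over the list alone, camera adjusted p = 0.000139, 0.383 with an estimated correlation). On the same arrays 7 of 12 ventricular cardiomyocyte markers were lower and markers of fibroblasts, macrophages and endothelium were mostly higher. Kcnh2 was 2.91-fold lower (log2 -1.54 ± 0.13, adjusted p = 0.000122), Kcnv2 at least 1.68-fold lower, and Cacna1c changed by -1.002 ± 0.06 (adjusted p = 3.41e-05). Atp2a2, the calcium pump of the sarcoplasmic reticulum, was 1.21-fold lower (-0.27 ± 0.07, adjusted p = 0.0215). That call was lost without sham replicate 3 (-0.25, adjusted p = 0.0618) or sham replicate 4 (-0.27, adjusted p = 0.0526), while the mean of its probe sets gave -0.96, and its adjusted p ran from 0.00154 to 0.119 over the alternatives. In the renin-angiotensin and natriuretic peptide system, 4 of 14 genes were higher, 5 lower and 5 did not pass (9 when adjusted over the list alone, camera adjusted p = 0.433, 0.541 with an estimated correlation). Agtr1a was 4.07-fold, Adra1b at least 4.55-fold and Corin 1.75-fold lower, and Ace was 1.53-fold higher.

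Genes of the 3 mitochondrial lists were lower nearly throughout. Of 28 genes of fatty acid oxidation, 27 were lower, 0 higher and 1 did not pass, with a median of -1.27 (27 when adjusted over the list alone, camera adjusted p = 1.32e-09, 0.383 with an estimated correlation). Acot1 was 9.04-fold lower (log2 -3.18 ± 0.32, adjusted p = 0.000229), Decr1 3.08-fold (-1.62 ± 0.15, adjusted p = 0.000153) and Eci2 2.41-fold. Of 39 genes of oxidative phosphorylation, 37 were lower, 0 higher and 2 did not pass, with a median of -0.61 (38 when adjusted over the list alone, camera adjusted p = 3.81e-11, 0.383 with an estimated correlation). Ndufs4 was 2.64-fold and Ndufs3 1.94-fold lower. Of 17 genes of the tricarboxylic acid cycle, 16 were lower, 0 higher and 1 did not pass, with a median of -0.79 (17 when adjusted over the list alone, camera adjusted p = 5.27e-07, 0.383 with an estimated correlation). Fh1 was 2.08-fold, Idh3g 1.73-fold and Cs 1.47-fold lower. Sham replicate 4, the array with the most liver transcripts, held the highest sham value in 2 of the called genes of fatty acid oxidation, 3 of oxidative phosphorylation and 0 of the cycle. On the same arrays 7 of 12 ventricular cardiomyocyte markers were lower, and 11 of 15 fibroblast, 12 of 16 macrophage and 9 of 15 endothelial markers were higher, so these falls were measured in tissue whose cell type markers also differed.

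**Figure D3:**
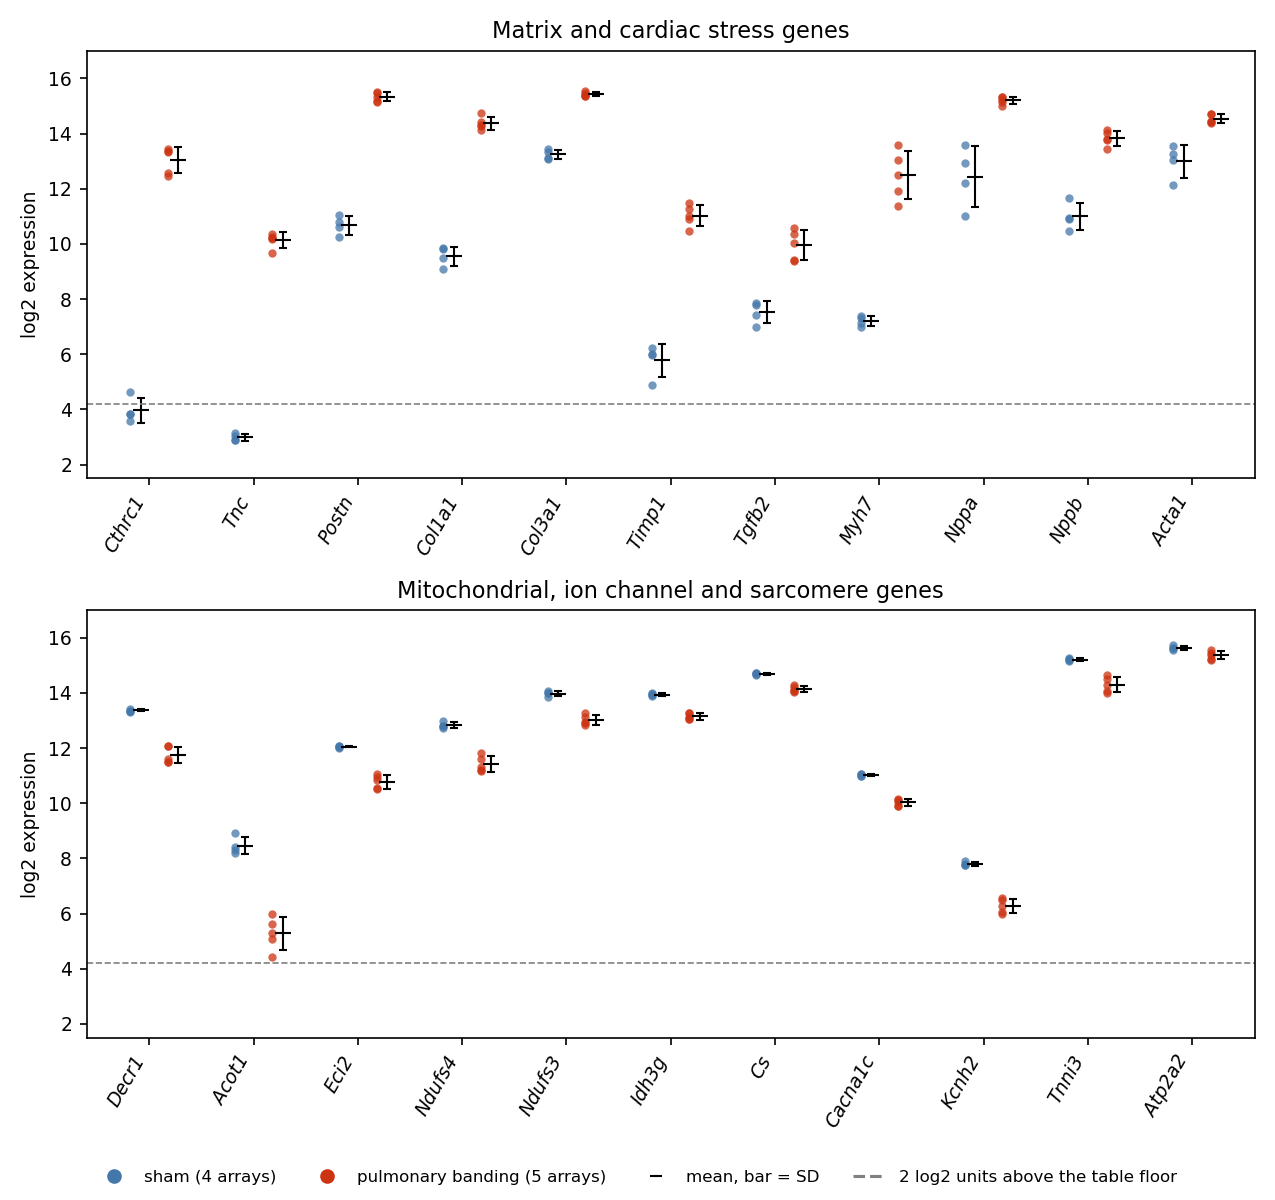
Log2 expression (vertical axis) of matrix and cardiac stress genes and of mitochondrial, ion channel and sarcomere genes, each point 1 of 4 sham or 5 banding arrays, with the mean, the SD as a bar and a dashed line at the dim level. Cthrc1 averaged 3.97 in sham and 13.04 in banding, and Nppa 12.44 and 15.20.

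Genes of proliferating cells were higher in banding, with 22 of 25 cell cycle genes higher, 1 lower and 2 not passing (23 when adjusted over the list alone, camera adjusted p = 2.71e-07, 0.383 with an estimated correlation). Cdk1 rose 9.5-fold (log2 3.25 ± 0.40, adjusted p = 0.000506), Top2a 8.56-fold (log2 3.10, or 1.18 with the mean of its probe sets) and Mcm6 2.34-fold. Of 21 immediate early genes, 17 were higher, 0 lower and 4 did not pass (18 when adjusted over the list alone, camera adjusted p = 3.45e-06, 0.383 with an estimated correlation). Egr3 rose at least 28.2-fold (log2 5.26, or 2.63 with the mean of its probe sets) and Egr2 23.9-fold, against 1.28 ± 0.11 log2 units for Junb and 1.10 ± 0.14 for Jun. Of 27 interferon response genes, 16 were higher, 1 lower and 10 did not pass (19 when adjusted over the list alone, camera adjusted p = 9.04e-05, 0.541 with an estimated correlation), with Irf7 2.81-fold and Bst2 2.77-fold higher. Of 15 complement genes, 9 were higher, 1 lower and 5 did not pass (10 when adjusted over the list alone, camera adjusted p = 0.00495, 0.383 with an estimated correlation). C1qb rose by 1.81 ± 0.23, Clu by 1.78 ± 0.16 and C1qa by 1.06 ± 0.07, and Cd59a changed by -1.93 ± 0.09. The banding values of Clu reached the highest value in the table, 16.43, so its rise can be compressed.

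**Figure D4:**
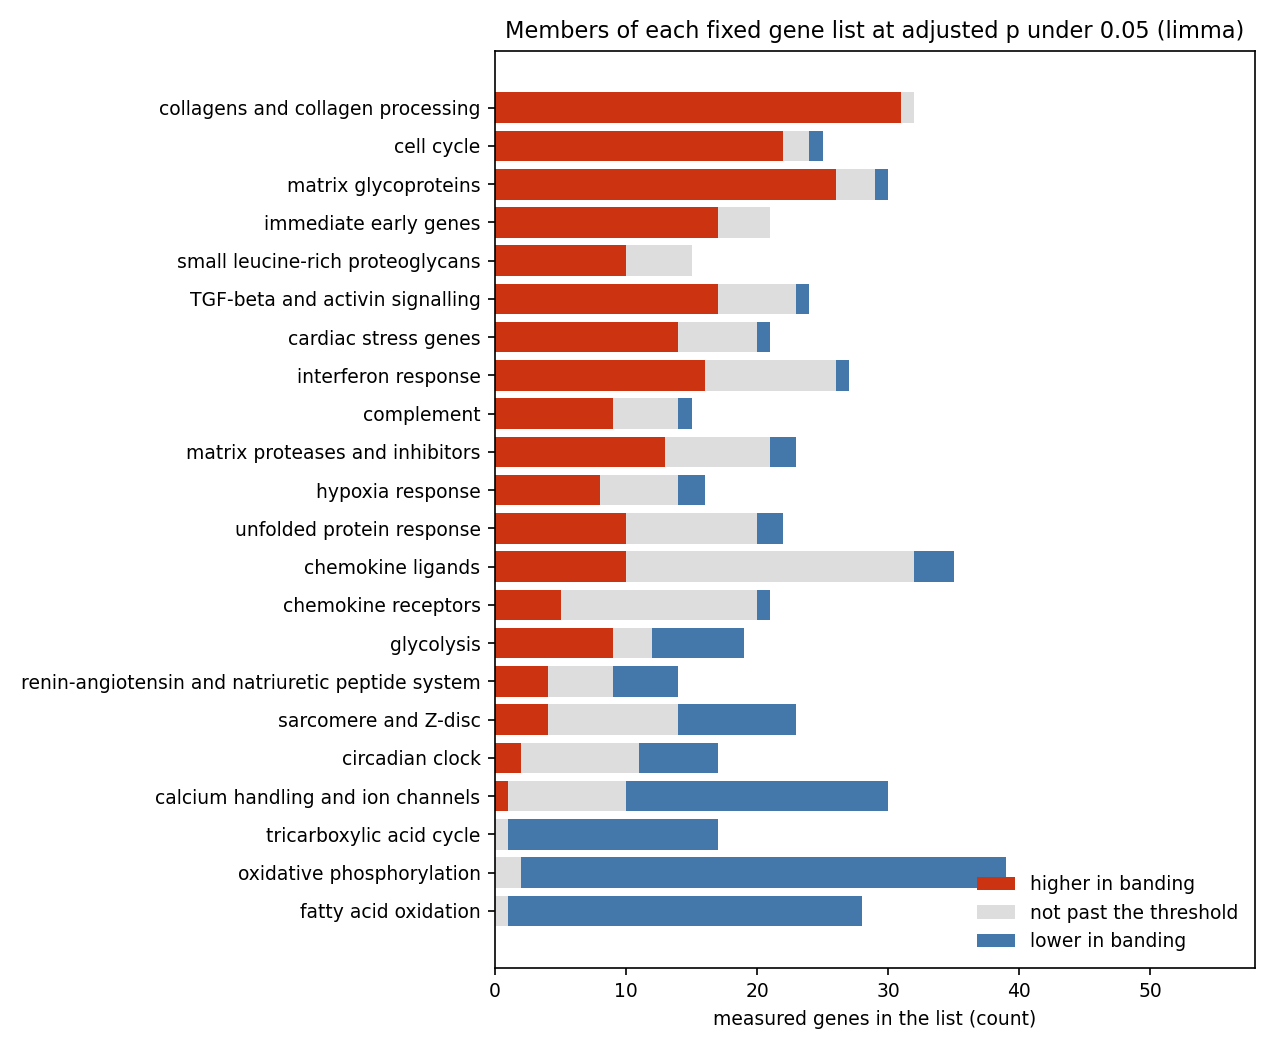
Count of measured genes (horizontal axis) in each fixed gene list that were higher in banding, lower or not past the threshold, 5 banding against 4 sham arrays. Cell cycle genes had 22 of 25 members higher, and oxidative phosphorylation had 37 of 39 lower.

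Markers of several cell types were also compared. All 12 activated fibroblast markers were higher (12 when adjusted over the list alone, camera adjusted p = 4.32e-10, 0.0943 with an estimated correlation), and of 15 fibroblast markers 11 were higher, 2 lower and 2 did not pass (13 when adjusted over the list alone, camera adjusted p = 0.000514, 0.383 with an estimated correlation). Pdgfrl rose by 3.79 ± 0.19 and Mfap5 by 3.12 ± 0.14. Of 16 macrophage markers, 12 were higher, 3 lower and 1 did not pass (15 when adjusted over the list alone, camera adjusted p = 0.000514, 0.383 with an estimated correlation). Ms4a7 rose 9.55-fold, Fcgr1 5.85-fold and Adgre1 2.72-fold. With the mean of its probe sets the rise was 1.74 log2 units for Ms4a7 (against 3.26) and 1.59 for Fcgr1 (against 2.55). The 3 lower macrophage genes, chosen after their values were seen, were Timd4 (at least 1.41-fold lower, adjusted p = 0.000175), Folr2 (2.63-fold, adjusted p = 0.00475) and Cd163 (1.98-fold, adjusted p = 0.00421). Of 15 endothelial markers, 9 were higher, 0 lower and 6 did not pass (10 when adjusted over the list alone, camera adjusted p = 0.00207, 0.469 with an estimated correlation), with Cdh5 up by 0.87 ± 0.16 and Egfl7 by 0.58 ± 0.09. Of 12 ventricular cardiomyocyte markers, 7 were lower, 0 higher and 5 did not pass (10 when adjusted over the list alone, camera adjusted p = 0.0124, 0.524 with an estimated correlation), with Irx4 at -1.23 ± 0.18.

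Of 12 smooth muscle and pericyte markers, 8 were higher, 1 lower and 3 did not pass (10 when adjusted over the list alone), with Mcam up by 1.88 ± 0.16 and Pdgfrb by 1.46 ± 0.11. That list's camera adjusted p of 0.0255 rose to 0.427 with an estimated correlation, 0.0543 with the mean of all probe sets, 0.0760 without cross-hybridising probe sets, 0.0543 without dim genes and 0.0546 with values floored. Lymphatic endothelial markers split, with Pdpn up by 1.62 ± 0.11 and Lyve1 at -1.73 ± 0.26 among 2 higher and 3 lower of 6 (5 when adjusted over the list alone, camera adjusted p = 0.768, 0.894 with an estimated correlation). For lymphocytes, 1 of 8 B cell markers was higher, namely Jchain (at least 2.82-fold, adjusted p = 0.0123), which did not pass with values floored (adjusted p = 0.0853), within a range of 0.00212 to 0.0853 over its alternatives. The B cell list had a median just below 0 and a mean of 0.50 (camera adjusted p = 0.606). Of 13 T and NK cell markers 1 was higher, Thy1, by 1.93 ± 0.22 (camera adjusted p = 0.495). Thy1 is also on the fibroblast list. In both groups 12 of these 13 and 6 of the 8 B cell markers were dim, so these lists could hardly show a change in lymphocytes.

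The remaining marker lists did not pass the camera test. Adjusted over the list alone, each of them, and those of B cells and of T and NK cells, had as many genes past the threshold as over all genes, except that neutrophils had 0. The atrial cardiomyocyte list had 2 of 12 higher and 4 lower (adjusted p = 0.814), with a mean of 0.05 and a median of 0.17 against a test direction downwards. The adipocyte list had 1 of 10 higher and 2 lower (adjusted p = 0.768), the skeletal muscle list 1 of 12 higher and 1 lower (adjusted p = 0.501), and the erythrocyte list 2 of 5 lower (adjusted p = 0.433). For mast cells 1 of 9 was higher (adjusted p = 0.443), and for neutrophils 1 of 8 (adjusted p = 0.626). The mesothelium and valve list had 3 of 11 higher and 2 lower (adjusted p = 0.788), and the Schwann cell and neuron list 1 of 8 higher and 1 lower (adjusted p = 0.983). No gene passed among 6 of lung epithelium (adjusted p = 0.857) or 7 of thymus (adjusted p = 0.719), and 1 of 4 sex-linked genes was lower (adjusted p = 0.606). All 6 lung epithelium genes and 6 of the 7 thymus genes were dim in both groups. In all, camera placed 23 of 43 lists past the threshold with a preset correlation and 0 with an estimated correlation (5 at an unadjusted p under 0.05), while fry found changes in either direction in 36.

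Of 17 circadian clock genes, 2 were higher, 6 lower and 9 did not pass (2 higher and 7 lower when adjusted over the list alone, camera adjusted p = 0.283, 0.573 with an estimated correlation). Hlf changed by -1.95 ± 0.23, Cry2 by -1.07 ± 0.12 and Tef by -0.90 ± 0.16, and Bhlhe40 rose by 0.51 ± 0.06. Chosen after their values were seen, Arntl rose at least 2.06-fold (adjusted p = 0.00555) and Ciart changed by -2.48 ± 0.48 (adjusted p = 0.00463). The rise of Arntl was 2.08 log2 units, or 1.04 with the mean of its probe sets. With values floored it did not pass (log2 1.04, adjusted p = 0.0783), and its adjusted p ran from 0.00125 to 0.0783 over the alternatives.

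Technical measures were compared between the 5 banding and 4 sham arrays with exact permutation tests, two-sided. The 14 hybridisation controls, added to every sample after labelling, averaged 10.06 ± 0.10 in banding (SD, n = 5) and 10.55 ± 0.20 in sham (SD, n = 4; exact p = 0.00794). The 3' minus 5' difference of the Actb control probe sets was 0.86 ± 0.03 in banding and 1.06 ± 0.08 in sham (exact p = 0.00794, 0.0635 after adjustment over the planned measures), and that of Gapdh did not differ beyond the spread (exact p = 0.262). The percentage of probe sets at the floor was 31.3 in banding and 29.8 in sham (exact p = 0.00794). Array medians (exact p = 0.175) and interquartile ranges (exact p = 0.159) did not differ beyond the spread. Marker means gave exact p-values of 0.0397 for erythrocytes (0.159 after adjustment), 0.119 for adipocytes, 0.278 for skeletal muscle and 0.929 for atrial cardiomyocytes. On sham replicate 4 the skeletal muscle markers averaged 6.97, against 4.67 to 5.08 on the other sham arrays and 4.66 to 5.02 on the banding arrays.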

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

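Of the tests in this part, that of the largest falls alone, at 4 log2 units or more, the ratio of the excess on 2 sham arrays and the share of lower genes at the level of the controls were chosen only after the result was seen, and the liver index as a covariate was added after the liver transcripts were seen.

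Within each group, the highest and lowest array was compared with its nearest neighbour for every named gene and technical measure, as the share of the group's range that lies in that gap. A share above the 95% critical value of Dixon's test singled out 29 of 305 groups, where chance gives 5%. Banding replicate 5 accounted for 12 of these and sham replicate 4 for 5.

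In 12 of the 29 the values were those of liver transcripts. On banding replicate 5 the gap was 1 for Serpina1c, Serpina1b, Apoa1, Cyp3a11, Hpx and Fgg. For these genes the other banding arrays shared 1 value under the dim level, so any higher value on banding replicate 5 gives a gap of 1. The gap was 0.908 for Fga, 0.843 for Alb, 0.842 for Ttr, 0.734 for Fabp1 and 0.856 for the mean of the liver genes seen first. On sham replicate 4 the liver index stood at 1, against 0.115 or lower on the other shams (gap 0.917).

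Other gaps lay in single genes. Sham replicate 4 was apart for C1qtnf3 (1), Epyc (0.901), Hk1 (0.870) and Edem1 (0.873), sham replicate 2 for Col11a1 (0.934), Ccl5 (0.885), Cxcr5 (1) and Fcgr1 (0.876), and sham replicate 3 for Corin (0.898), Egr3 (1) and Jchain (1). Banding replicate 1 was apart for Timd4 (0.871) and for the percentage of probe sets at the floor (0.881), banding replicate 2 for Jun (0.881) and P4ha1 (0.792), banding replicate 4 for Tnc (0.744) and banding replicate 5 for Cdh5 (0.827). The values of Cxcr5, and of C1qtnf3, Col11a1 and Jchain in sham, lie at or near the floor. Those of Egr3 and Ccl5 in sham and of Timd4 in banding lie under the dim level. No cause was tested for these.

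Liver transcripts were higher on all 4 sham arrays, and their levels differed widely among them. This difference between the groups was not shared by other genes of like level. The median difference of the 39 held-out liver genes was -3.16 log2 units, while 1000 lists matched on mean expression gave medians between -0.23 and 0.35. Normalisation between arrays holds such medians near 0, so the comparison cannot decide on a shift of intensities at hybridisation. RNA from liver carried into the samples would, as one source, keep its genes in 1 ratio. All 36 held-out genes above the dim level on some array averaged higher in sham and had their highest sham value on sham replicate 4. The full order of albumin, sham replicates 4, 1, 2 and 3, was found in 69.4% of them (25 of 36), where chance gives 4.17%. That share lies between the marks set beforehand, 80% for this source and 50% against it, so this source stays open. Lower transcription in the banded ventricle cannot be told apart from it, because the 15 held-out genes above the dim level on all shams varied 10.6 times as much over them as genes of like level (4.54 against 0.43 log2 units), which a programme that varies between animals would also give.

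The genes at least 2-fold lower are, as a whole, not explained by these transcripts, since 23.3% of them had their highest sham value on sham replicate 4, where chance gives 25%. Their excess over banding on the linear scale was 0.921 times as large on sham replicate 4 as on sham replicate 3 (median), while the ratio was 12.4 to 380 for the 19 held-out liver genes that passed. The share on sham replicate 4 grew with the fall, from 13.2% of 804 genes at 1 to 2 log2 units to 63.6% of 55 genes at 3 to 4 and 92% of 75 genes at 4 or more. Many of the genes at 4 or more are the liver genes seen first, so that share partly restates what prompted the test. RNA from liver in the sham samples may be the source of many of the largest falls. The liver index as a covariate decides nothing here, since 46 of 49 liver genes stayed past the threshold under it. Of 816 genes that differed at least 2-fold at the level of the lower hybridisation controls, 44.0% were lower (359, against 457 higher). The 10 controls at that level differed by a median of -0.60 log2 units, banding minus sham. Normalisation between arrays tends to balance rises and falls, so that share cannot decide on a shift common to genes of one level. An artifact specific to single probe sets and an effect of banding were not tested.

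A score of the Arntl phase against the Dbp phase was 1.53 higher in banding (exact permutation p = 0.0159), although the clock list did not pass camera and 5 of the 15 genes in the score had been looked at before. Over the other 10 genes alone the score was 1.28 higher (exact permutation p = 0.00794, the smallest these group sizes can give). RNA from liver is argued against, as the excess over banding of 9 Dbp-phase genes was 1.66 times as large on sham replicate 4 as on sham replicate 3 (median, highest 2.86), against at least 12.4 for the held-out liver genes that passed. Collection at another time of day may account for the difference, since 90% of the clock genes not looked at beforehand (9 of 10, of which 1 was dim in both groups) went the way of their phase, and 5 of them passed the threshold. An effect of banding on the clock cannot be told apart from this, because collection times are not given in the sources used here.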

How the results depend on the processing

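The liver index as a covariate, leaving out sham replicate 4 with banding replicate 5, and the floor at the dim level were chosen after seeing the data. The rest were planned.

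Single genes were not tracked under all probe sets tested singly, the 1.5-fold minimum or the adjusted p of 0.01. Under the other alternatives 122 of 138 genes tracked kept their side of the threshold, and only Cxcl13, which did not pass, changed direction. The number past the threshold was 6270 to 6701 when each array was left out in turn and 6177 to 7653 over the other settings that kept the threshold and 1 value per gene, apart from the replicate block. All probe sets tested singly gave 11670 past the threshold, 5746 higher and 5924 lower, because 45037 were tested. A 1.5-fold minimum left 4551, of which 2217 were lower, and an adjusted p of 0.01 left 5235. The planned floor at the 20th percentile equals the floor of the table and moved nothing.

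A block on replicate number, without banding replicate 5, gave 5277 genes (2549 higher, 2728 lower), and 73.1% of the calls stayed. Deviations of same-numbered arrays correlated at -0.03 to 0.04 across genes, so no signal shared by them was seen. This cannot show whether same-numbered samples were handled together. Under the block Epyc, Ccl8, Ccl2, Tgfb1, Acta1, Atp2a2, Jchain, Tef, Hk1 and Pgam2 no longer passed. With the liver index, 6630 passed and 88.3% of the calls stayed, among them 46 of 49 liver genes, so the index does not remove liver transcripts.

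Camera with an estimated correlation placed 0 lists past the threshold, with 0.381 for the proteoglycans and 0.383 for the chemokine ligands and receptors, where 39 of 43 lists had an estimated correlation above the preset 0.01. With the directional test of fry 26 lists passed, and with the mixed test 36, against 23. The joint chemokine list had an adjusted p of 0.0552 with the liver index, and 0.0143 to 0.0400 when each array was left out. The cause was not tested. For small leucine-rich proteoglycans that range was 9.81e-05 to 0.00033.

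Reversals were found only in results that did not pass, and their cause was not tested. Centring turned the list tests of atrial cardiomyocyte (0.955), Schwann cell and neuron (0.955) and lung epithelium (0.941). The block turned glycolysis (0.956) and mesothelium and valve (0.959). The liver index turned skeletal muscle (0.501) and Schwann cell and neuron (0.963). Leaving out sham replicate 4 with banding replicate 5 turned mesothelium and valve (0.973) and Schwann cell and neuron (0.973). Fry turned chemokine ligands (0.997), glycolysis (0.550) and lymphatic endothelial (0.727). When each array was left out, some runs turned Schwann cell and neuron (0.810 to 0.973), thymus (0.603 to 0.979), mesothelium and valve (0.592 to 0.9998) and the difference of Cxcl13 (-0.062 to 0.327).

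Signal near the floor limits what can be seen, since 7180 genes were dim in both groups and folds against a dim group are lower bounds.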

Other observations

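The genes named here outside the fixed rule were chosen after their values were seen, and the split test at the end was planned.

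Glycolysis genes went both ways. Of 19 genes, 9 were higher, 7 lower and 3 did not pass (16 when adjusted over the list alone, camera adjusted p = 0.857, 0.899 with an estimated correlation). Pfkp rose by 1.77 ± 0.21 log2 units, while Slc2a4, the insulin-responsive glucose transporter, changed by -1.52 ± 0.21, Ldhb by -0.91 ± 0.10 and Hk2 by -0.55 ± 0.05. Of the genes picked after their values were seen, Pgam1 rose by 1.16 ± 0.18 and Hk1 by 0.58 ± 0.12, and Pfkm changed by -0.92 ± 0.19 and Pgam2 by -0.59 ± 0.15. The adjusted p of Hk1 ran from 0.00168 to 0.0838 over its alternatives, and that of Pgam2 from 0.00114 to 0.0648, the latter without sham replicate 4 and banding replicate 5. No test compared the members of an enzyme family.

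Of 16 hypoxia response genes, 8 were higher, 2 lower and 6 did not pass (10 when adjusted over the list alone, camera adjusted p = 0.0856, 0.564 with an estimated correlation). The list passed without banding replicate 3 (0.0479) and with arrays centred on their medians (0.0238). Hmox1 rose by 1.84 ± 0.32, P4ha1 by 1.07 ± 0.14 and Ndrg1 by 0.72 ± 0.11. Of 22 unfolded protein response genes, 10 were higher, 2 lower and 10 did not pass (13 when adjusted over the list alone, camera adjusted p = 0.015, 0.524 with an estimated correlation). Edem1 rose by 1.35 ± 0.18 and Pdia3 by 1.04 ± 0.08, and Herpud1 changed by -0.85 ± 0.12.

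Against the 12 of 16 macrophage markers that were higher, Timd4, Folr2 and Cd163 were lower, with log2 differences of -2.28 ± 0.22, -1.39 ± 0.27 and -0.99 ± 0.19. These 3 were picked after their values were seen, and no fixed list or test separates kinds of macrophage.

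A chance split of the arrays is argued against for the number of genes past the threshold, within what 100 splits can show. The test cannot separate banding from other differences that follow the groups, such as that of the hybridisation controls. Of 100 splits of the 9 arrays into 5 and 4, drawn at random, only the real 1 gave as many as 6989 genes. The highest other gave 4935, with banding replicate 1 grouped with the 4 sham arrays, the next gave 15, and 95 gave 0.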
